A study of Bos taurus with 6 samples.

How the data were processed

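RNA of 3 superstimulated and 3 non-superstimulated cows was measured on 6 two-colour arrays, as 3 cow pairs with a dye swap each. Per the labels' protocols, RNA was extracted with Trizol, amplified in 2 rounds with T7 RNA polymerase and labelled with Cy3 and Cy5 by a chemical linkage to guanine. Amplification of very small inputs can distort levels, and the ratio within an array removes only what both channels share. The deposited scanner tables hold foreground and local background intensity per spot for a green (Cy3) and a red (Cy5) laser, not background-subtracted, per the file headers. The scanner settings and software are not given in the sources used here. A deposited table of log2 values was used as an alternative. Its normalization is not given in the sources used here. By correlation with the normalized scanner ratios of the same arrays (0.739 to 0.868, and at most 0.335 with another array) it holds red over green on a log2 scale, with column medians of -0.00431, -0.0113, -0.035, -0.011, -0.00625 and -0.00788 for arrays 1 to 6.

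Each array held 45220 spots. The 8 spots without a name and 42 spots that the scanner software marked as ignored on any array were left out, which left 43753 probes and 1417 control spots. Foreground means were corrected for the background medians with normexp and an offset of 50 on all remaining spots. Ratios were normalized within each array by loess with control spots at weight 0, and no step between arrays was applied. A probe was kept if it exceeded the 95th percentile of 756 negative control spots in at least 1 channel on at least 3 of 6 arrays, which left 31957 probes. This used R 4.3.3 and limma 3.58.1; figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

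Of 43794 probes on the array, 21790 had 1 gene symbol in the platform annotation, none had several and 22004 were unnamed here. Symbols came from that annotation, which can be old, and were updated by name through a RefSeq gene table of the ARS-UCD2.0 assembly. There, 20068 matched a symbol, 1644 an unambiguous synonym and 78 nothing, and these kept the platform's name. No coordinates were used. A gene was represented by its probe with the highest mean intensity, which gave 12332 genes. Of 2895 genes with several probes, 1240 had probes of opposite sign.

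The arrays of a swap were turned to superstimulated over non-superstimulated and averaged, since they share their extracts. The mean of 3 pairs was tested against 0 with limma's lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels say that the 3 cows of a group are different animals. Levels per cow came from separate channels after loess and Aquantile. They were used to check the pairing and the spread between cows, for the unpaired fit, and for the levels of single genes given below. Cows with the same number deviated from their group means with correlations across genes of 0.177, 0.04 and 0.272, and cows with different numbers with -0.259 to 0.23. Cows with the same number shared their arrays, so effects of spot and array can enter these correlations. Deviations from a mean of 3 cows also sum to 0, which ties the correlations to each other. They therefore do not show whether the animals of a pair were matched. The 24 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Single pairs were tested in a limma model of 6 arrays with a term per pair and 1 for dye, whose error is that of the swap.

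The rule for named genes, also fixed before the data were examined, took the 12 genes with the largest positive and the 12 with the largest negative mean ratio past the threshold with 1 sign on all 6 arrays. Where fewer passed, it took those with the smallest p among genes at an unadjusted p under 0.05, at least 2-fold and of 1 sign on all 6 arrays. It added 18 fixed genes and up to 4 members of each list with the smallest p. Genes with placeholder names were left out.

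The steps were tested on simulated data for this comparison with 12332 genes, of which 200 were changed. With the real spread between pairs, the test recovered 32% of genes changed 2-fold, 50% of those changed 4-fold, 76% of those changed 16-fold and 90% of those changed 64-fold, with 10 false calls. With the smaller spread of the dye swaps these shares were 92%, 98%, 100% and 100%. The test of differences between pairs recovered 42%, 82%, 92% and 100% of these sizes, with 2 false calls. Each gene's estimated SD was taken as its true spread, although it rests on few arrays, and all 200 changed genes shared 1 adjustment. The shares may therefore overstate what the test finds. In the real data RAB15, at a mean log2 ratio of -1.56 ± 0.11 (SD, n = 3 pairs), had an adjusted p of 0.995 by limma. Of the lists, camera called the 1 that was shifted and 0 others. The simulated genes were independent of each other, so this does not test the preset correlation on genes that move together. In the real data the lists that passed had estimated correlations of 0.12 to 0.82.

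Alternatives covered the background correction, within-array and between-array normalization, the filter, the model of the replicates, single slides, the prior, the deposited values, the threshold, the choice of probe, the dye assignment and each pair left out. Keeping the ignored spots, and the differences between pairs with their alternatives, were added after seeing the data.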

Results

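Gene expression was compared between superstimulated and non-superstimulated cattle on 6 two-colour oligonucleotide arrays. Superstimulation is a course of gonadotropin injections that lets many ovarian follicles grow at once. Per the labels, the animals were multiparous beef cows and the samples were dissected and snap frozen; the labels used here name no tissue, and give gonadotropins as the hormone treatment for both channels of each array, the reference group included. Each group had 3 cows. Cow 1 of one group was hybridised against cow 1 of the other, and likewise for cows 2 and 3, and each pair was repeated with the dyes exchanged, so that a pair was 1 replicate and n was 3 pairs. Arrays 1 to 3 lay on 1 slide and the swapped arrays 4 to 6 on another. The median probe intensity was 152 to 299 in the red (Cy5) channel and 161 to 283 in the green (Cy3) channel. Between 47.3% and 63.2% of the probes exceeded the negative controls in red, and between 65.4% and 71.2% in green. The number of arrays limits the precision of every value below.

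The direction of every ratio is unsettled in the sources used here. The dye fields of the 6 arrays put the superstimulated cow in Cy5 on arrays 1 to 3, whereas the example in the series' design text puts it in Cy3, which would turn every sign. Ratios are given as superstimulated over non-superstimulated by the array fields, and "higher" or "lower" means on that scale.

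Between superstimulated and non-superstimulated cows, the largest ratio among the higher genes chosen by the fixed rule was that of NTS, which encodes the peptide neurotensin, with a mean log2 ratio of 3.57 ± 1.27 (SD, n = 3 pairs). FOS, an immediate early transcription factor, followed with 2.88 ± 1.79. The endoplasmic reticulum proteins HSPA5, the main chaperone of that compartment, and MANF had 1.48 ± 0.67 and 1.20 ± 0.65. OAT, a mitochondrial enzyme of ornithine metabolism, had 1.39 ± 0.59, LAPTM4A 1.37 ± 0.92, the actin nucleation subunit ACTR3 1.34 ± 0.64 and POFUT2, which adds fucose to secreted proteins, 1.21 ± 0.26. SARAF, a regulator of store-operated calcium entry, had 1.10 ± 0.30, SULT4A1 1.08 ± 0.57, HIGD1A 1.03 ± 0.69 and GCH1, the first enzyme of tetrahydrobiopterin synthesis, 1.02 ± 0.61.

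Among the lower genes, MTARC2 had a mean log2 ratio of -2.07 ± 1.02, RALYL -1.95 ± 0.58 and SELENOP, the plasma selenium carrier, -1.95 ± 0.74. LRRC49 had -1.85 ± 1.01. RAB15, a small GTPase, varied least between pairs on its brightest probe, with -1.56 ± 0.11 and pair values of -1.46, -1.53 and -1.68. SERPINA5, an inhibitor of serine proteases, had -1.48 ± 0.43, the transcription factor FOXP2 -1.25 ± 0.59, the linker histone H1-3 -1.19 ± 0.32 and the protease inhibitor SPINT2 -1.15 ± 0.43. KCNIP4 had -1.12 ± 0.53, SLC37A1 -1.09 ± 0.57 and ALPK1 -1.07 ± 0.41. These 24 genes kept their sign on all 6 arrays, and none passed the threshold. For 9 of them another probe of the gene gave a smaller ratio: -0.01 for FOS, 0.02 for SULT4A1, -0.04 for GCH1, 0.305 for LAPTM4A, -0.13 for RAB15, -0.22 for RALYL, -0.15 for SPINT2, -0.04 for KCNIP4 and -0.79 for H1-3. In the non-superstimulated channel NTS and POFUT2 exceeded the negative controls on 4 of 6 arrays and SULT4A1 on 2, and in the superstimulated channel ALPK1 did so on 2 and SULT4A1, FOXP2, KCNIP4 and SLC37A1 on 5.

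**Figure D1:**
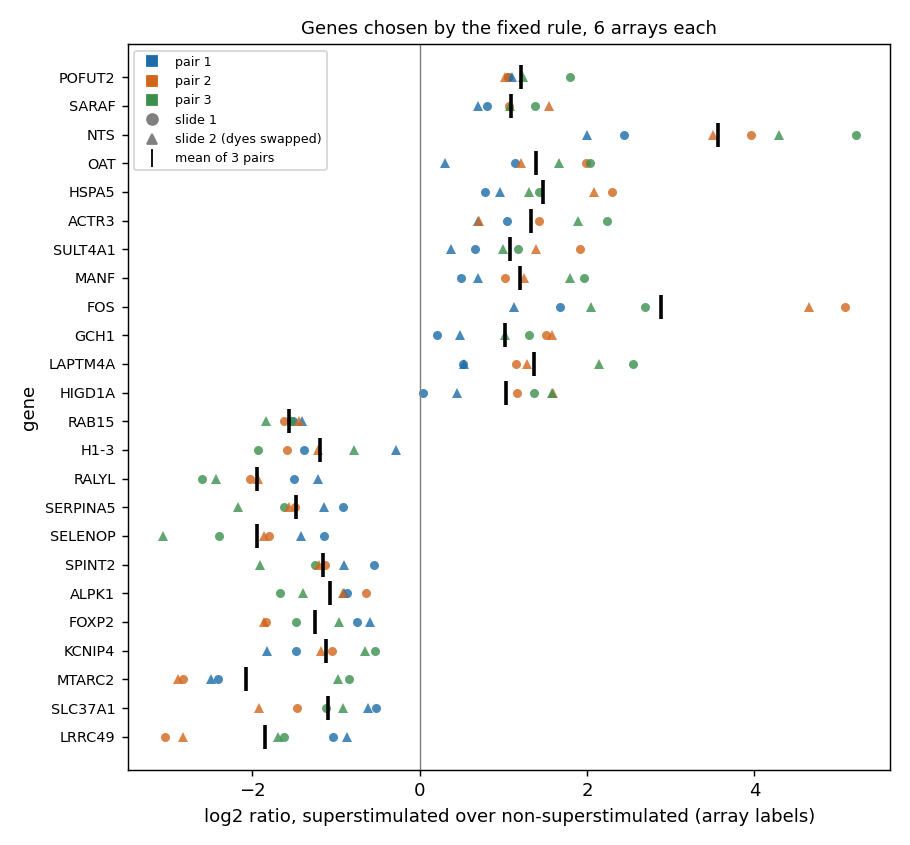
Log2 ratio of superstimulated over non-superstimulated (x axis, by the array dye fields) for the 24 genes of the fixed rule (y axis). Colours mark the 3 cow pairs, circles and triangles the 2 slides with opposite dyes, and black bars the mean of 3 pairs. All 6 arrays of each gene lie on the same side of 0, and RAB15 spans the narrowest range of pair values, -1.46 to -1.68.

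With limma, 0 of 12332 genes and 0 of 31957 probes passed an adjusted p of 0.05, and the lowest adjusted p was 0.995 for genes and 0.999 for probes. At an unadjusted p under 0.05 there were 443 genes, 164 higher and 279 lower, where 617 would be expected by chance. Of these, 57 differed at least 2-fold, 15 higher and 42 lower. The excess of lower genes, 73.7%, turned round without pair 1, with 184 higher and 147 lower genes, and on the swapped slide alone, with 75 and 47, and was smaller in the authors' deposited values, with 61 and 79. The same sign in all 3 pairs was seen for 23.0% of the genes, where chance gives 25%.

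Genes of follicular steroid synthesis did not share 1 direction. STAR, which carries cholesterol into the mitochondrion, had a log2 ratio of -2.39 in pair 1, 0.22 in pair 2 and -0.37 in pair 3. HSD3B1, which makes progesterone from pregnenolone, had -1.90, -3.22 and 1.84. CYP11A1, the side chain cleavage enzyme, had -0.11, 1.30 and 0.13. The aromatase CYP19A1 had -0.30 ± 0.96 (SD, n = 3 pairs), although another of its probes lay at 0.265, and CYP17A1 had 0.02 ± 0.09. The receptor FSHR was lower in each pair, with -0.53 ± 0.30, and LHCGR had -0.05 ± 0.62. INHBA, the activin subunit, was bright in both channels with a ratio of 0.03 ± 0.20, and FST, which binds activin, had -0.13 ± 0.89.

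PGR, the progesterone receptor, had log2 ratios of 0.11, 4.48 and 0.78 in pairs 1, 2 and 3. PTGS2, the inducible prostaglandin synthase, had -1.59, -1.88 and 4.12. The matrix glycoprotein THBS1 was higher in each pair, with 2.06, 6.08 and 0.69, and FN1 had -0.07, 2.59 and 4.26. The growth factor IGF2 had 0.14, 2.08 and 3.83, although another of its probes lay at 0.03. VEGFA had 0.10 ± 0.14 (SD, n = 3 pairs). The oxidative stress genes HMOX1 and NFE2L2 had -0.28 ± 0.46 and 0.68 ± 0.69. In the superstimulated channel PTGS2 and CYP17A1 exceeded the negative controls on 2 of 6 arrays, LHCGR on 3 and VEGFA on 5, and in the other channel THBS1 and CYP17A1 did so on 3, LHCGR on 4 and PTGS2 and VEGFA on 5. None of these 18 genes fixed in advance passed the threshold, and LHCGR, CYP19A1, CYP17A1, PTGS2, INHBA, FST and VEGFA changed sign under at least 1 other setting.

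**Figure D2:**
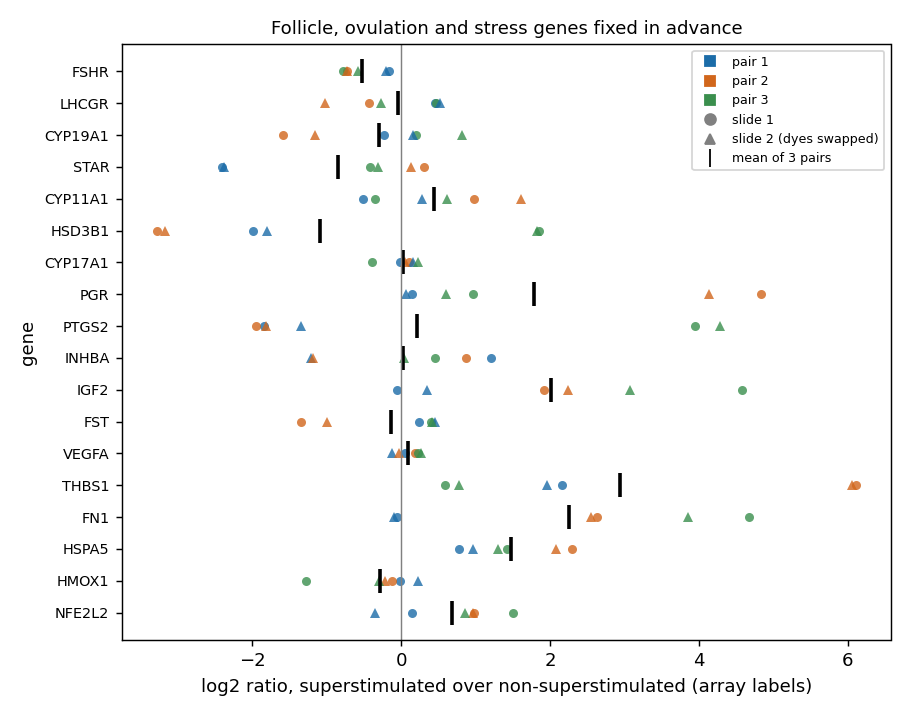
Log2 ratio of superstimulated over non-superstimulated (x axis, by the array dye fields) for 18 genes fixed in advance (y axis). Colours mark the 3 cow pairs, circles and triangles the 2 slides with opposite dyes, and black bars the mean of 3 pairs. PTGS2 lies at -1.59 and -1.88 in pairs 1 and 2 and at 4.12 in pair 3.

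Of 24 gene lists, 5 passed limma's camera test with a preset correlation, all of them higher. None of these calls held with an estimated correlation, where each of the 5 had an adjusted p of 0.79 or 0.85. That form of the test has only 2 residual degrees of freedom, so a lost call does not by itself show that correlated genes were the reason. The endoplasmic reticulum stress list had a median log2 ratio of 0.39 over 22 measured genes, with 20 higher and 2 lower (adjusted p = 1.3e-07), and medians of 0.01, 0.72 and 0.50 in pairs 1, 2 and 3. Beside HSPA5, its chaperones CALR and HSP90B1 had 0.68 ± 0.35 and 1.35 ± 1.01 (SD, n = 3 pairs), although another probe of HSP90B1 lay at 0.32. The list of genes that respond to luteinizing hormone had a median of 0.72 over 25 genes, with 23 higher (adjusted p = 1.3e-05), among them NTS and TIMP1, a protease inhibitor, at 1.86 ± 2.0. Extracellular matrix genes had a median of 0.31 over 34 genes with 27 higher (adjusted p = 0.00029), COL4A2 having 0.68 ± 0.38 and SPARC -0.44 ± 0.27. Respiratory chain genes had a median of 0.26 over 30 genes with 20 higher (adjusted p = 0.0074), COX4I1 having 0.63 ± 0.33. Immediate early genes had a median of 0.25 over 21 genes with 14 higher (adjusted p = 0.01), DUSP1 having 1.23 ± 1.25. Each of these 4 lists had a median below 0 in 1 pair. In pairs 1, 2 and 3, luteinizing hormone response genes had -0.05, 1.26 and 0.74, and matrix genes -0.05, 0.10 and 0.67. Respiratory chain genes had 0.06, -0.16 and 0.82, and immediate early genes 0.02, 0.97 and -0.01. TIMP1 exceeded the negative controls on 4 of 6 arrays in the superstimulated channel, and COL4A2 on 5 there and on 3 in the other. No member of any list passed, over all genes or adjusted over the list alone. The call for respiratory chain genes was lost without pair 3 (median -0.06), that for immediate early genes without pair 2 (-0.06), and that for luteinizing hormone response genes without pair 3 (0.33), as was that for matrix genes (0.04). On the swapped slide alone the calls for matrix and immediate early genes were lost (medians 0.24 and 0.49), and on the forward slide alone that for respiratory chain genes (0.28). The call for respiratory chain genes was also narrowly lost when the cows were taken as unpaired.

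The other 19 lists did not pass in the main analysis. Cell cycle genes had median log2 ratios of -0.07, -0.80 and 0.52 in pairs 1, 2 and 3, and glycolysis and hypoxia genes 0.03, -0.34 and 0.91. Ribosomal protein genes had 0.14, 0.16 and -0.37, and granulosa cell markers 0.00, -0.29 and -0.05. Cell cycle genes passed as lower without pair 3 (adjusted p = 2.6e-05) and as higher without pair 2 (0.0068), and ribosomal protein genes as higher without pair 3 (6.5e-08) and on the forward slide alone (0.035), all with the preset correlation. The estimated correlations of these lists were 0.53 and 0.66, with which both had an adjusted p of 0.92 over the 3 pairs. Over the 3 pairs the median was 0.03 for steroidogenesis, 0.11 for cholesterol synthesis, 0.03 for follicle growth, 0.05 for angiogenesis, 0.10 for the NRF2 response, 0.12 for apoptosis and 0.07 for TGF-beta signalling. It was -0.05 for the interferon response and 0.00 for inflammation. The remaining cell type markers had medians of 0.01 for theca and stroma, -0.02 for endothelium, 0.01 for leukocytes, -0.04 for red cells, 0.05 for oocytes and -0.02 for epithelium. These medians do not show an unchanged mixture of cells. Only 3 of 12 endothelial and 2 of 13 leukocyte members exceeded the negative controls on all arrays in both channels. Of the theca and stroma members, 10 were higher and 8 lower. The camera direction was upward for ribosomal proteins, glycolysis and epithelial markers although their medians lay below 0, and the mean of the follicle growth list was -0.02.

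**Figure D3:**
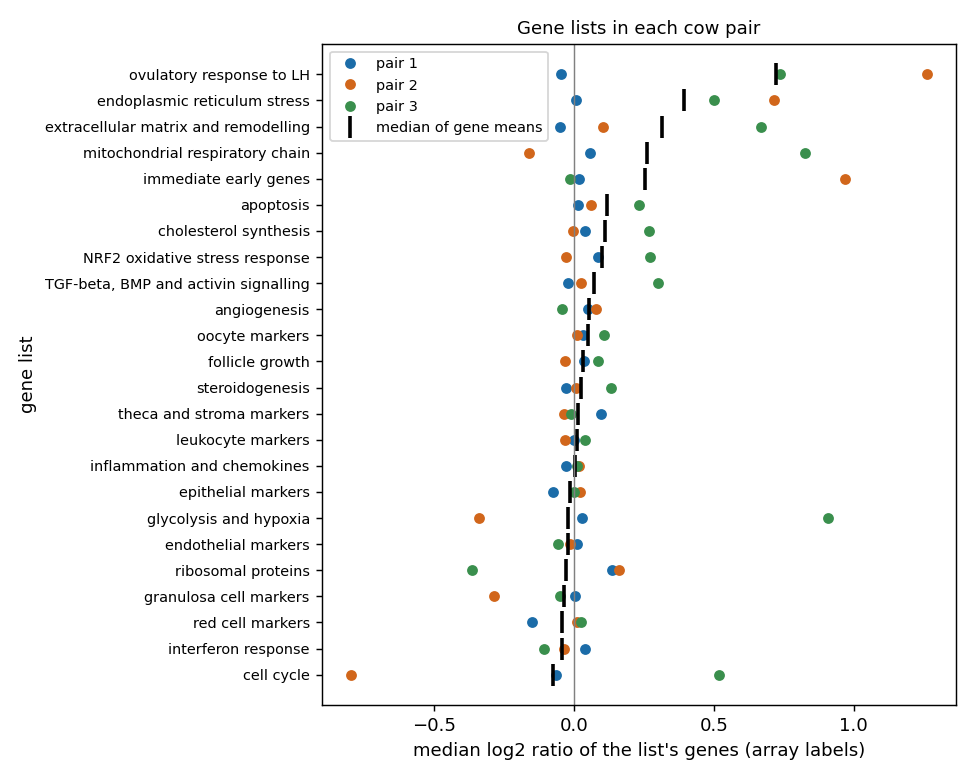
Median log2 ratio of superstimulated over non-superstimulated (x axis, by the array dye fields) of the genes in each of 24 lists (y axis). Points mark the 3 cow pairs and black bars the median of the genes' means over 3 pairs. The luteinizing hormone response list lies at -0.05 in pair 1, 1.26 in pair 2 and 0.74 in pair 3.

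The cow pairs differed from each other. Measured against the error of the dye swap, which is technical and says nothing of other cows, the ratio differed between pairs for 6298 genes, or 51.1% (2136 genes in the authors' deposited values). At an adjusted p of 0.05 against that error, 472 genes in pair 1 were higher and 853 lower, with 1705 and 2693 in pair 2 and 3365 and 2418 in pair 3. Of 758 genes that passed in all 3 pairs, 173, or 22.8%, went the same way, 49 higher and 124 lower, where the signs in each pair give 23.8% by chance. They included NTS, THBS1, FOS and FSTL3 among the higher genes and NRP1, MYH11, LTF, SELENOP and RAB15 among the lower. In the deposited values that count was 6. Of these named genes, FSTL3, NRP1 and MYH11 were among the 4 members of a list with the smallest p, and LTF was chosen after its values were seen.

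Of 1011 genes that passed in both pair 1 and pair 3, 621, or 61.4%, went opposite ways, where the signs in each pair give 52.3% by chance. For pairs 1 and 2 the share was 43.3% against 46.7% by chance, and for pairs 2 and 3 it was 51.9% against 51.9%. GFRA1, a receptor of the glial cell line-derived neurotrophic factor family, had -4.61 in pair 1 and 5.75 in pair 3, CLDN11, a tight junction protein, -3.31 and 5.77, and TNFAIP6, a hyaluronan-binding protein of the cumulus matrix, -4.01 and 4.68; these 3 genes were chosen after their values were seen. Across genes, which are not independent replicates, the ratios of pairs 1 and 3 correlated at -0.186, those of pairs 1 and 2 at 0.005 and those of pairs 2 and 3 at 0.076.

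Dye cancels in the mean of a pair. All arrays of 1 dye orientation shared a slide, so a difference between the slides in red over green does not cancel. Such a difference could not be separated from the group ratio. The part of the ratio that followed the dye passed the threshold for 11211 of 31957 probes by limma. Its median size was 0.13 on the log2 scale, against 0.09 for the group ratio. This count was 2893 without pair 1 and 1401 in the deposited values.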

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

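Keeping the ignored spots, and every alternative for the differences between pairs, were chosen after seeing the data. Only the fit of 6 arrays as independent brought a gene past an adjusted p of 0.05, and no alternative a probe. At an unadjusted p and 2-fold there were 106 probes and 57 genes, which moved with the setting: 11 genes with an eBayes trend, 99 without within-array normalization, 137 on the forward and 122 on the swapped slide, 154 with 6 independent arrays, 166 with the pair as a random block and 140 in the deposited values. Without pair 1 it was 331, without pair 2 44 and without pair 3 62, of which 50, 21 and 12 were among the 57. Taking the 6 arrays as independent, which counts each extract pair as 2 replicates, gave 1 gene, RAB15. With the pair as a random block, the paired count was 0 genes and 0 probes, and the unpaired fit of 3 cows against 3 also gave 0 and 0. Compared with the 6 arrays taken as independent, the block removed the call of RAB15. The lowest adjusted p of a gene by limma was 0.38 with the block and 0.03 without it. Without pair 1, 2 or 3 the counts were 0 to 0. The dyes as in the design text turn every sign, so that 73.7% rather than 26.3% of the 57 genes would be higher. Aquantile leaves ratios as they are. Of the lists, 5 passed under most settings, 3 on the swapped slide, 0 with an estimated correlation, 0 by fry and 0 by its mixed test, and 4 to 5 without a pair. These were not the same lists: at the preset correlation cell cycle genes passed as lower without pair 3 and as higher without pair 2, and ribosomal protein genes as higher without pair 3 and on the forward slide. The median of immediate early genes ranged from -0.06 to 0.51 without a pair and that of respiratory chain genes from -0.059 to 0.42. The dye count was 18699 without within-array normalization, 1401 in the deposited values and 2893 to 13913 without a pair. The deposited values gave 2136 genes that differ between pairs, and the cause was not tested.

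Among 41 named genes, 845 of 859 values under other settings kept their direction and their side of the threshold. LHCGR, at -0.05, had 0.17 on the forward slide, 0.015 in the deposited values and -0.31 to 0.30 without a pair. CYP19A1 had -0.70 to 0.24 and FST -0.41 to 0.38 without a pair. CYP17A1 had -0.10 on the forward slide and -0.004 to 0.076 without a pair. PTGS2 had -0.019 with a normexp offset of 16 and -1.74 to 1.26 without a pair. INHBA had -0.016 without within-array normalization, -0.78 on the swapped slide and -0.078 to 0.125 without a pair. VEGFA had -0.018 in the deposited values. The cause was not tested. Keeping the ignored spots widened the fitted background SD of array 2 in green from 9.3 to 161.4, where the lowest foreground minus background was -15172 rather than 7, and gave 5849 genes that differ between pairs and 8683 dye probes. The offset of 50 pulls ratios of dim probes toward 0.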

Other observations

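The tests of array noise in pairs 2 and 3 and of exchanged groups in 1 pair were chosen after the result was seen. So were those of correlated list members and of cell shares, and the counts over other signs for genes. The other tests were written down before their own outcome. Those on the absence of genes past the threshold, on the endoplasmic reticulum stress list and on pairs 1 and 3 still address patterns seen in these data.

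KRT8, LUM and MYH11 were among the list members with the smallest p. KRT8, an epithelial keratin, had a log2 ratio of 5.23 in pair 2 and -0.01 and -0.02 in pairs 1 and 3, with a level of 12.7 in superstimulated cow 2 against 7.5 in its partner, and 11.5 in both cows of pair 3. LUM, a matrix proteoglycan, had -0.06, 4.03 and 4.38. MYH11, a smooth muscle myosin, had -0.92, -1.10 and -4.25, and its level was 11.6 in non-superstimulated cow 3 and 6.02 to 7.83 in the other 5 cows. In the superstimulated channel MYH11 exceeded the negative controls on 3 of 6 arrays and in the other on 5.

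With 3 pairs there are 4 patterns of sign, so that no share under 0.05 can be reached. The real pattern gave 0 genes past the threshold and the highest other 0, so 4 of 4 were as large. It gave 57 genes at an unadjusted p and 2-fold against a highest other of 89, and 3 of 4 were as large. It gave 5 lists, as did each of the other patterns, so 4 of 4 were as large; the endoplasmic reticulum stress list was not among them with pair 2 or pair 3 turned (adjusted p = 0.61 and 0.8), and was with pair 1 turned (1.7e-06).

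No gene passed although single pairs changed by many fold. Array noise is argued against in pairs 2 and 3, whose swapped arrays correlated at 0.724 or more across genes, and in pair 1 noise as the whole cause, at 0.394 over the brightest 25% of genes, although pair 1 reached only 0.305 over all genes and a larger share of noise there stays open. The swapped arrays share their extracts, so these correlations do not cover earlier steps. Distortion in dissection or extraction, or in amplification if that was shared, would repeat on both arrays and stays open. An exchange of the groups in 1 pair cannot be told apart, because the pairs as labelled hardly correlate (0.005, -0.186 and 0.076): turning pair 1 raised the lowest correlation to -0.005 and the count at an unadjusted p and 2-fold from 57 to 89, with 0 genes past the threshold either way. Cows at different stages of the ovulatory response are a candidate explanation: the luteinizing hormone response list varied more between cows of a group than 100% of 10000 random lists of equal brightness, with a median SD of 1.59 against at most 0.83 for another list. This does not single out the ovulatory response, because 12 of 24 lists varied more than 95% of their random lists, and a difference between cows in treatment response stays open and untested.

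The endoplasmic reticulum stress list was higher by the array fields in pairs 2 and 3, with medians of 0.72 and 0.50, and not shifted in pair 1, at 0.01. Abundant genes in general are argued against, since 0 of 10000 random lists of equal brightness had a median as high. A dye bias is argued against too, since the list's median was 0.408 or more on each slide. A slide bias common to all pairs is argued against as the whole cause. It would shift pair 1, which lay on the same slides, as much as pairs 2 and 3, yet pair 1 had 0.01 against 0.72 and 0.50. A slide bias offset by an opposite change in pair 1, or a bias of single arrays, cannot be told apart, because the slide changed together with the dye orientation. The call was lost by camera with an estimated correlation (adjusted p = 0.79), but that test has only 2 residual degrees of freedom. A list with an estimated correlation under 0 also lost strength with it. The NRF2 response, at -0.03, went from an unadjusted camera p of 0.072 to 0.18. Whether genes that move together in single pairs account for the call is therefore not decided, although this list's estimated correlation was 0.38. A response to superstimulation stays open, as does its sign.

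Genes past the threshold in both pair 1 and pair 3 changed the opposite way in 61.4% of cases, against 52.3% by chance. A different share of red cells is not decided by the globin genes HBA and HBB. Their log2 levels were at most 7.22 in all 6 cows against a median of 7.75 over all genes. HBA lay near the negative controls, above them on 4 of 6 arrays in the superstimulated channel and on 5 in the other. Levels of different probes need not be comparable either. A different share of endothelial cells, leukocytes or theca cells cannot be told apart from other causes: the endothelial and leukocyte lists had medians of at most 0.058 in size, but only 3 of 12 and 2 of 13 members exceeded the negative controls on all arrays, the bright leukocyte gene PTPRC, chosen after its values were seen, had 0.22 in pair 1 and -1.02 in pair 3, and the theca and stroma genes spread both ways in pair 3, with an SD of 1.82. An exchange of the groups in either pair cannot be told apart either: 43.3% and 51.9% of the genes shared with pair 2 went opposite ways, and the bound set before was wrong, since signs taken by chance give 46.7% and 51.9%. A response to superstimulation that differs between cows stays open and untested.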
